A study of Mus musculus with 2 samples.

How the data were processed

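CTCF ChIP-seq was measured in newborn mouse intestine in 1 group of 2 biological replicates, as the labels name them. Peak lists on mm10 were used for each replicate, for the pooled reads and for 2 lists filtered by IDR, called optimal and conservative. Per the descriptions deposited with the files, the pooled list was made from the alignments of both replicates and a further file of unstated role, and the IDR lists from the replicates' lists and the pooled list. Aligner, peak caller, versions, IDR threshold and the role of any control are not given in the sources used here, and no control track was used here.

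The peak signal is the enrichment value the authors deposited for each peak, with its normalization not stated, and it was used to describe and rank peaks within a list. Across lists it entered only the rank correlation of the replicates and the match of optimal with pooled peaks. The deposited −log10 q-value and the deposited score of each peak were not used in any result. The summit was taken from the offset the authors deposited. In 99.9% of cases an optimal peak had the interval of a pooled peak and its signal within 0.01. Of the conservative intervals 90.7% were also in the optimal list, so the conservative list is not a subset of it. Of the optimal peaks 50.7% were 310 bases wide, 97.1% of those below the median signal and 4.30% of those above it. The lists give no read counts, so intervals cover counting of peaks and not sequencing depth.

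Chromosomes 1 to 19 and X of the mm10 sequence were used with GENCODE annotation M21; chromosome names and lengths were compared with the lists first. Peaks on unplaced scaffolds and on Y were counted but not annotated. A summit was assigned to 1 class in the order promoter (1 kb around any TSS), 5' untranslated region, coding sequence, 3' untranslated region, other exon, intron and intergenic. The null for classes rotated all summits of a chromosome by a common offset over sequenced bases, 1000 times, leaving out runs of 1000 or more unknown bases.

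The motif matrix was trained from the seed CCASYAGRKGGCR on the 5000 strongest peaks of even-numbered chromosomes, in 6 rounds with a pseudocount of 1, and scored on the other chromosomes. The score threshold was the one that 5% of training flanking windows reached. The training rule was not fully fixed before the data were examined. A first matrix kept only the better-scoring training sites in each round; it called no motif at H19 and some other named genes. It was then replaced by a matrix of all training sites, which is the one reported. This choice was made after seeing the results, partly because of the missing H19 motif, and it raised the share of peaks with a motif from 72.8% to 76.8%; the motif share, the convergent share, the odds ratio of a motif at promoters and the count of named genes with a motif are given with both. Motif shares by class and decile, the split by distance, the loci and the genomic instances are given with the reported matrix alone.

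Neighbouring motif strands were permuted 10000 times. For 18 gene lists fixed before the data were examined, the share of genes with a summit within 10 kb of any TSS was set against 10000 random lists matched on gene length decile and biotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. Named genes followed a rule fixed at the same time: the 10 strongest peaks within 10 kb of a protein-coding TSS; in each list the 2 genes with the strongest summit and the first without one; H19, Igf2, Cdx2, Vil1, Lgr5, Myc, Ctcf and Xist; and the densest 1 Mb window and widest gap. Of the genes this rule takes, 2 are not reported here. Other genes named as members of a list, as apolipoprotein genes or in a gap were chosen after their values were seen.

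Alternatives were the conservative list, peaks above the median signal, each replicate alone, other windows, thresholds and overlap rules, and rotated peaks as the background of the gene lists. Leaving out a replicate meant taking the strongest 73465 peaks of the other. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0, pysam 0.24.0, matplotlib 3.10.9 and samtools 1.23.1 was used. Simulated data were used to test the promoter share, motif share, strand order, gene lists, replicate agreement, odds ratio, word search and Fisher's test. The X ratio, the correlation with gene density and the genomic motif instances were not simulated. For promoters, 40 sets of 5000 uniform peaks gave 0 calls. Of planted motifs 87.5% of 1212 were called, and of windows without one 5.58% of 788. By p under 0.05, 2 of 40 sets of random strands passed, and 9 of 200 random and 198 of 200 planted lists of 25 genes did. In the gene list simulations genes were bound independently of each other, and planted lists at 90% against 55%. They do not show how the test behaves for clustered genes or for smaller differences.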

Results

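CTCF is a zinc-finger protein that binds DNA at a long sequence motif, marks boundaries of chromatin domains and blocks contacts between enhancers and promoters. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole intestine of newborn mice (postnatal day 0, strain B6NCrl). There was 1 group of 2 biological replicates, each made from powdered intestines of several dissections, and the sex of the mice was not recorded. The series has no other condition, so the values describe where CTCF was found and no difference between conditions was tested. Coordinates are on the mouse assembly mm10, and peak signal is the authors' own value from their peak caller, used here to describe and rank peaks within a list and, between replicates, by rank alone.

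Each replicate's list held 300000 peaks, and so did the list from the pooled reads. The optimal list, thresholded on the irreproducible discovery rate (IDR, a measure of how alike peaks rank in replicate lists), held 73465 peaks covering 19.96 Mb, and the conservative IDR list held 70556. Optimal peaks had a median signal of 76.0, with a range of 4.48 to 756. Read depth is unknown from the files, so weak peaks cannot be set against the number of reads behind them.

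Genes of the intestinal epithelium's transcription factors stood close to CTCF peaks without exception. All 24 of them, including Cdx1, Cdx2, Hnf4a, Gata4, Klf5 and Sox9, had an optimal summit within 10 kb of a transcription start site (TSS), against 75.1% ± 8.57 (SD) in 10000 random lists matched on gene length and biotype (adjusted p = 0.02, permutation test, two-sided). Cdx1, a homeobox factor of the intestinal epithelium, had a peak of signal 442 at 3.808 kb upstream of its TSS. Cdx2, a master regulator of intestinal identity, had 1 summit within the window, 7.94 kb from its nearest TSS, with a signal of 297. With a window of 50 kb 24 of 24 genes were bound, the most possible, against 89.2% in matched lists (adjusted p = 0.17, permutation test).

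The lists of differentiated epithelial markers did not pass the test against matched genes. Among enterocyte genes of the brush border and of lipid handling, 21 of 26 had a summit within 10 kb (80.8% against 74.9% ± 8.27 in matched lists, adjusted p = 0.64, permutation test). Apob, the structural protein of chylomicrons, had a peak of signal 512 at 0.948 kb from its TSS. Espn, an actin bundler of microvilli, had 14 summits within 10 kb of any of its 13 TSSs, the strongest with a signal of 507. Vil1, which encodes the brush border protein villin, had a promoter peak of signal 185 at 0.657 kb upstream of its TSS. Fabp1, a fatty acid binding protein, had none within 10 kb. Of the secretory lineage genes, 18 of 24 were near a summit (75% against 70.1% ± 9.02, adjusted p = 0.69, permutation test), with Clca1 and Tff3, both goblet cell genes, at signals of 466 and 452, and with no summit within 10 kb of Atoh1, the factor that specifies the lineage.

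Crypt stem cell and Wnt target genes had a summit in 19 of 21 cases (90.5% against 78.7% ± 8.64, adjusted p = 0.37, permutation test). Ccnd1 (signal 541), a cell cycle regulator, and Smoc2 (signal 497) led this list. Lgr5, the receptor that marks crypt stem cells, had a peak of signal 142 at 0.037 kb from its TSS, and Myc had 4 summits within 10 kb, the strongest with a signal of 350 at 1.959 kb upstream. Olfm4, another crypt marker, had none.

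None of the lists of other cell types of the gut wall passed the test. The enteric neuron and glia list had 20 of 21 genes bound (95.2% against 75.3% ± 9.22, adjusted p = 0.063, permutation test), led by Gfap at a signal of 542 and Nos1 at 421, with Edn3 unbound. Smooth muscle and mesenchyme genes had 21 of 23 bound (91.3% against 73.4% ± 9.01, adjusted p = 0.089, permutation test), led by Nkx3-2 at 560 and Smtn at 533, while Actg2 had no summit. Among peaks above the median signal the smooth muscle list did pass (82.6% against 56.6%, adjusted p = 0.031, permutation test). Of blood and immune genes 17 of 24 were bound (70.8% against 71.0% ± 8.92, adjusted p = 1, permutation test), led by Cd79a at 573 and Spi1 at 480, with none at Cd8a; at 2 kb the immune list was lower than matched genes (25% against 50.4%, adjusted p = 0.038, permutation test). Genes of other organs had 16 of 24 bound (66.7% against 72.8% ± 8.83, adjusted p = 0.69, permutation test). That list shares Gfap with the glial list. Mbp, a myelin gene, had a signal of 528 there, and Alb, the main plasma protein of the liver, had no summit.

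Several gene families were bound more often than genes matched on length and biotype. Ribosomal protein genes had 73 of 76 members within 10 kb of a summit (96.1% against 62.3% ± 5.46, adjusted p = 0.0006, permutation test), where Rpl3l and Rps2 shared a peak of signal 596 and Rpl10l had none. Replication-dependent histone genes had 49 of 68 (72.1% against 50.2% ± 5.73, adjusted p = 0.0009, permutation test), with Hist1h2ah and Hist1h2bk sharing a peak of signal 459 and Hist1h1b unbound. Housekeeping genes had 17 of 18 (94.4% against 68.2% ± 10.8, adjusted p = 0.034, permutation test), with Rplp0 at 564, Tubb5 at 546 and the X-linked Hprt unbound. The housekeeping call was lost in the conservative list, where 16 genes were bound (adjusted p = 0.11, permutation test), and at 2 kb (72.2% against 46.9%, adjusted p = 0.065, permutation test). At 50 kb all 18 were bound, the most possible, against 84.4% in matched lists (adjusted p = 0.17, permutation test).

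Imprinted genes, which are expressed from 1 parental allele, had 35 of 39 members bound (89.7% against 71.7% ± 6.78, adjusted p = 0.02, permutation test), led by Plagl1 at a signal of 520 and Mcts2 at 481, and Snrpn had no summit within 10 kb. The call was lost with replicate 2 left out (adjusted p = 0.07, permutation test) and at windows of 2 kb (0.062) and 50 kb (0.29). Hox genes, which pattern the body axis, had 34 of 39 bound (87.2% against 68.2% ± 7.47, adjusted p = 0.032, permutation test), where Hoxa3 and Hoxa7 shared a peak of signal 569; the call was lost with replicate 1 left out (adjusted p = 0.074, permutation test), in the conservative list (0.064) and at 2 kb (0.84). Clustered protocadherin genes had 51 of 56 bound (91.1% against 76.4% ± 5.49, adjusted p = 0.02, permutation test), but mostly by weak peaks: the median signal at their strongest summit was 64.2, against 365 for Hox genes. Among the peaks above the median signal only 24 of the 56 protocadherin genes stayed bound, 42.9% against a matched 59.4% (adjusted p = 0.025, permutation test), so the direction turned. The call was also lost in the conservative list (adjusted p = 0.074), with replicate 2 left out (0.15) and at 50 kb (0.1), all by the permutation test. Pcdhga9 and Pcdhga10 shared the list's strongest peak (signal 256.1), and Pcdha7 had none.

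Chemosensory receptor genes were largely free of CTCF peaks. Of 1124 olfactory receptor genes 141 had a summit within 10 kb (12.5% against 62.3% ± 1.33, adjusted p = 0.0006, permutation test), and of 328 vomeronasal receptor genes 12 did (3.66% against 67.0% ± 2.47, adjusted p = 0.0006, permutation test). Olfr94 and Olfr95 shared a peak of signal 581, and Vmn1r21 had one of signal 379, whereas Olfr1 and Vmn1r100 had none. Whether reads could be placed uniquely at these receptor genes was not examined, so a missing peak need not mean missing CTCF. The cohesin and CTCF genes had 17 of 20 members bound (85.0% against 79.6% ± 8.84, adjusted p = 0.69, permutation test), led by Esco1 at a signal of 575 and Smc3 at 517; Ctcf itself had 4 summits within the window, the strongest of signal 356, and Wapl had none. Genes of the X inactivation region had 8 of 9 members bound (88.9% against 57.4% ± 15.5, adjusted p = 0.1, permutation test; 0.049 among peaks above the median signal), with Xist at a signal of 399, Jpx at 330 and Chic1 unbound. The 18 lists were 1 family of tests with Benjamini-Hochberg adjustment, and the random lists treat genes as independent, which neighbouring family members are not. The random lists were not matched on the number of TSSs or on local gene density. They were drawn from all annotated genes, including the seldom bound receptor genes. How far this sets the differences was not tested.

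**Figure D1:**
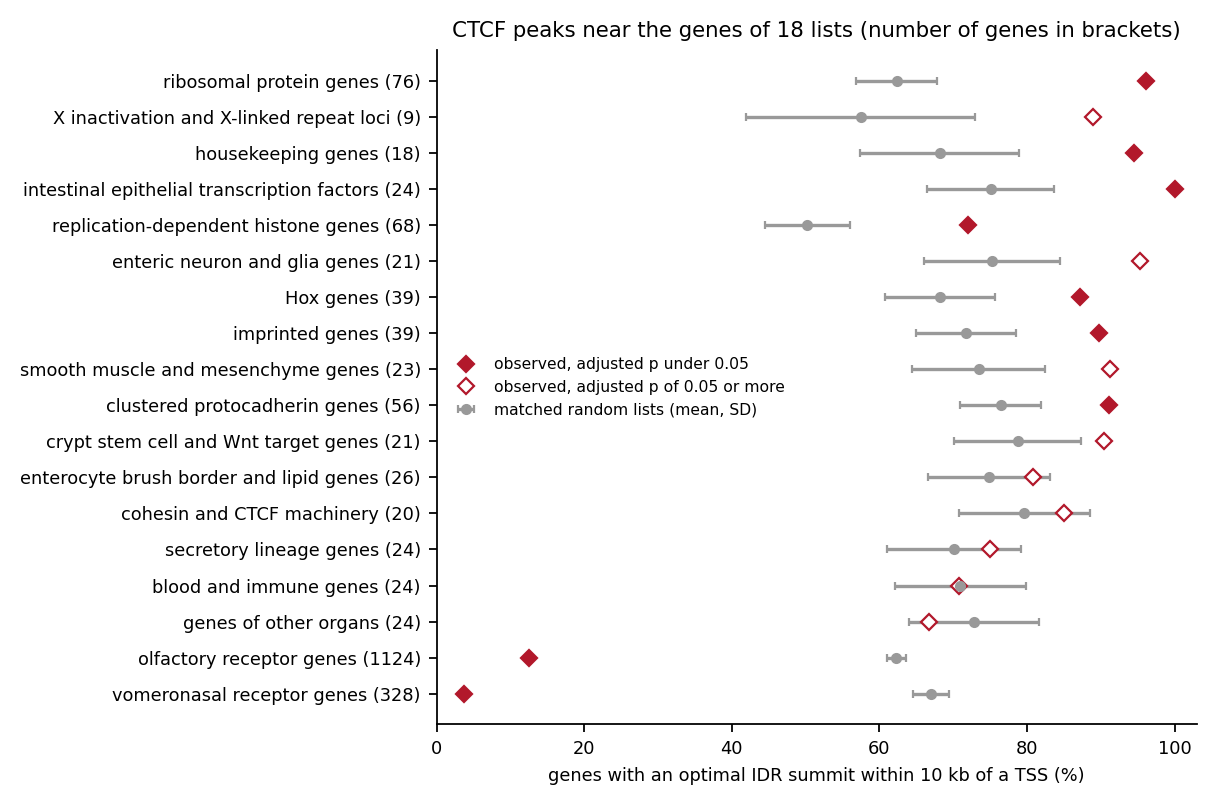
Share of genes (x axis, percent) with an optimal IDR summit within 10 kb of a TSS in 18 gene lists (y axis, number of genes in brackets). Diamonds are observed shares, filled where the adjusted p is under 0.05, and grey points with bars are the mean and SD of 10000 matched random lists; the olfactory (12.5%) and vomeronasal (3.66%) receptor genes lie far to the left of their matched lists.

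At the imprinted H19 and Igf2 locus on chromosome 7, CTCF peaks clustered upstream of H19. H19, a noncoding RNA at 142575529 to 142578143 on the minus strand, had 5 summits within 10 kb. The strongest of them (peak 142580633 to 142580880, signal 221) was intergenic, 2.62 kb upstream of the TSS, and held the motif CTACCGCGCGGTGGCAGCA at 142580762 on the minus strand. This H19 motif scored 9.93 against a threshold of 8.58. The first matrix did not call it and was replaced partly for that reason, so the call is no independent finding. Igf2, the fetal growth factor gene at 142650766 to 142666816, had 5 summits within 10 kb. The strongest had a signal of 353 at 5.51 kb upstream (peak 142672188 to 142672465). From 10 kb beyond H19 to 10 kb beyond Igf2 there were 11 peaks. With the reported matrix 9 held a motif, of which 7 lay on the minus strand. This span was chosen after the values of both genes were seen.

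**Figure D2:**
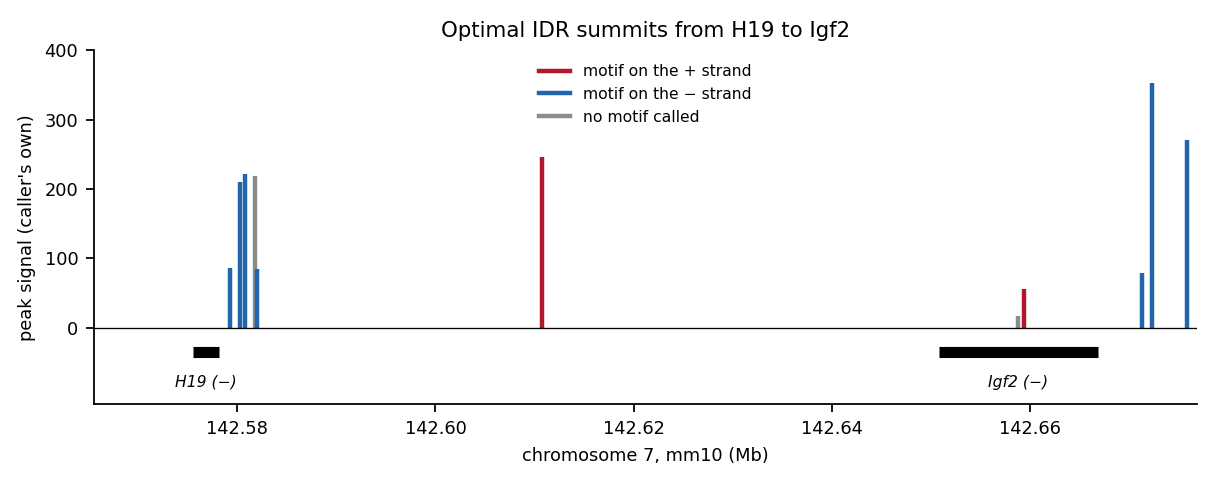
Optimal IDR summits between H19 and Igf2 on chromosome 7 (x axis, Mb on mm10), with the caller's own signal as line height (y axis, no unit). Colour gives the strand of the CTCF motif called with the reported matrix, and grey marks the 2 of 11 peaks with none. Black bars are the genes, both on the minus strand.

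The 10 strongest peaks within 10 kb of a protein-coding TSS had signals of 691 to 732. They lay at Nipsnap2 (732, at 0.075 kb from its TSS), Gdf15 (723), Acbd4 (721), Fam129b (719), Polr3gl (716), Fpgs (705), Nckap5l (701), Rrp1 (697), Iqsec1 (692) and Twf2 (691). All but Rrp1 held a CTCF motif, but the peaks at Gdf15, Fam129b, Fpgs, Rrp1 and Iqsec1 were among those that trained the motif matrix. Gdf15, which encodes a stress hormone, had its peak over coding sequence on chromosome 8 from 70629654 to 70630154, and the peaks of Fam129b and Fpgs were intronic. All 10 ranked among the strongest 25 peaks of each replicate's own list.

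Across all annotated genes, 29727 of 53843 (55.2%) had an optimal summit within 10 kb of a TSS, and 15877 of 21755 protein-coding genes (73.0%) did. Promoters, taken as 1 kb around any TSS, held 21.7% of the optimal summits, 3.39 times the 6.39% ± 0.188 (SD) found when the summits of each chromosome were rotated together 1000 times (p = 0.001, permutation test, two-sided, the smallest p that 1000 rotations can give). Coding exons held 1.83% against 1.03% ± 0.0479 (p = 0.001, permutation test), and 3' untranslated regions 1.68% against 1.26% ± 0.0566 (p = 0.001, permutation test). Introns held 40.5% against 40.3% ± 0.564 (p = 0.68, permutation test), but among peaks above the median signal they held 38.9%, below the rotated 40.3% ± 0.591 (p = 0.024, permutation test). Intergenic sequence held 32.7%, below the rotated 49.9% ± 0.69 (p = 0.001, permutation test). Rotated summits were not matched on local gene density, and how far this sets the differences between classes was not tested. The promoter share was 45.7% with 5 kb around the TSS (rotated 24.1%) and 10.4% with 200 bases (rotated 1.51%).

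The CTCF motif lay under most peaks. A 19-base matrix with the consensus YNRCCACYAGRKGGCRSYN, trained on peaks of even-numbered chromosomes, was found within 100 bases of the summit in 31480 of 40979 peaks of the odd-numbered chromosomes and X. This is 76.8% (95% Wilson interval 76.4 to 77.2), against 5.27% of flanking windows 1 kb away (odds ratio 59.6, log10 of the p of Fisher's exact test, two-sided, -14912). The share of flanking windows lies near 5% by the choice of threshold. Windows were taken on both sides of each peak, and the test treats peaks and windows as independent, which they are not. A matrix built first, from the better-scoring training sites alone, gave 72.8%, and the matrix reported here replaced it after that result had been seen. The motif centre lay a median of 7 bases from the summit. Motif score and peak signal had a Spearman rho of 0.364 across peaks, which are not independent replicates, with a matrix trained on strong peaks.

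Promoter peaks held the motif less often than peaks elsewhere. It was found in 58.7% of promoter peaks (interval 57.6 to 59.7), in 81.0% of intronic peaks (80.4 to 81.6) and in 84.2% of intergenic peaks (83.6 to 84.8). From signal decile 1, the weakest, to decile 10, the share rose from 51.4% to 96.8%. At named genes, the strongest summits of Vil1 (CCTACAGCAGAGGGCAGCA, chromosome 1 from 74408717), Lgr5 (GAGCCTGTAGAGGGCAGCG, chromosome 10 from 115587523), Cdx2 (AGGCCGCTAGGAGGCGCGT, chromosome 5 from 147299324) and Myc (TGGCCAGTAGAGGGCACAC, chromosome 15 from 61983428) all held a motif. Of 42 genes named by rule from the lists and loci with a summit in the window, 40 had a motif at their strongest summit, and Pcdhga9 and Pcdhga10 did not. With the first matrix the number was 35, and the motifs at H19, Xist, Esco1, Hist1h2ah and Hist1h2bk were not called. Most of the 42 genes were named for the strongest summits of their list, where a motif is more frequent, and some of these peaks trained the matrix. Over all bound genes of a list, the strongest summit held a motif in 34 of 51 protocadherin genes, the lowest share. The highest was 12 of 12 vomeronasal receptor genes.

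**Figure D3:**
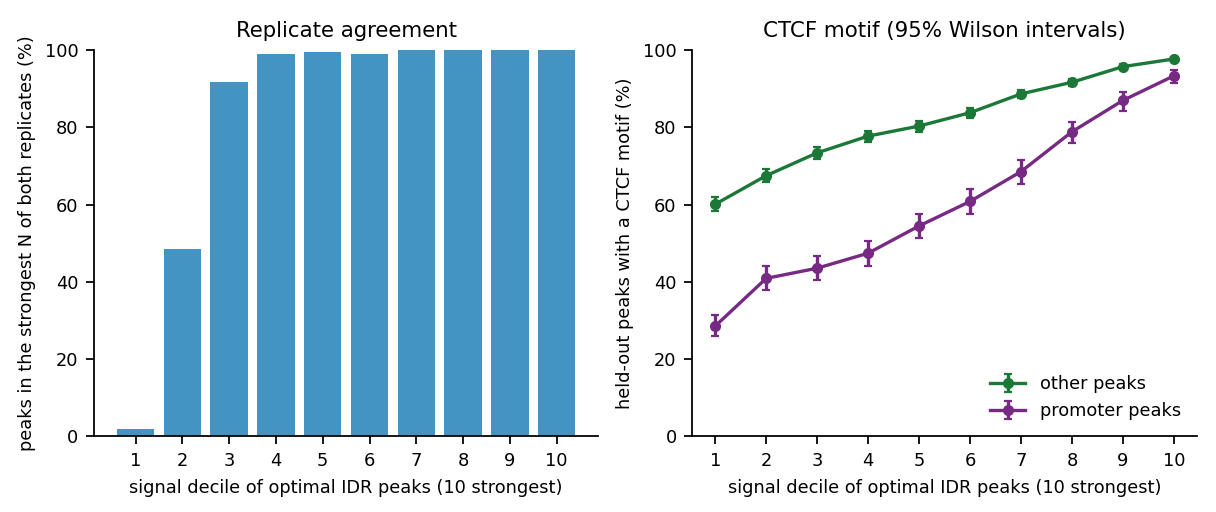
Left, percent of optimal peaks with a summit among the strongest 73465 peaks of both replicates (y axis) by signal decile (x axis, 10 the strongest). Right, percent of held-out peaks with a CTCF motif (y axis) by signal decile for promoter and other peaks, with 95% Wilson intervals; promoter peaks lie at 28.5% in decile 1 and 93.3% in decile 10, other peaks at 60.1% and 97.7%.

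Neighbouring motifs were more often in tandem than random strands would give. Of 56142 pairs of neighbouring motif-bearing peaks under 1 Mb apart, 23.5% were convergent, with motifs pointing at each other, against 25% ± 0.105 (SD) after 10000 permutations of the strands (p = 0.0001, two-sided, the smallest p they can give). Divergent pairs made up 23.6% (p = 0.0001) and tandem pairs 53.0% against 50% ± 0.21 (p = 0.0001, permutation tests). The split by distance was not planned. Convergent pairs were 22.4% (20.7 to 24.1) of the 2201 pairs under 1 kb, 20.1% (19.3 to 20.9) of the 10328 pairs at 1 to 5 kb and 31.7% (29.7 to 33.8) of the 1978 pairs at 200 to 1000 kb, while divergent pairs made up 23.6%, 25.1% and 15.9% of these.

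**Figure D4:**
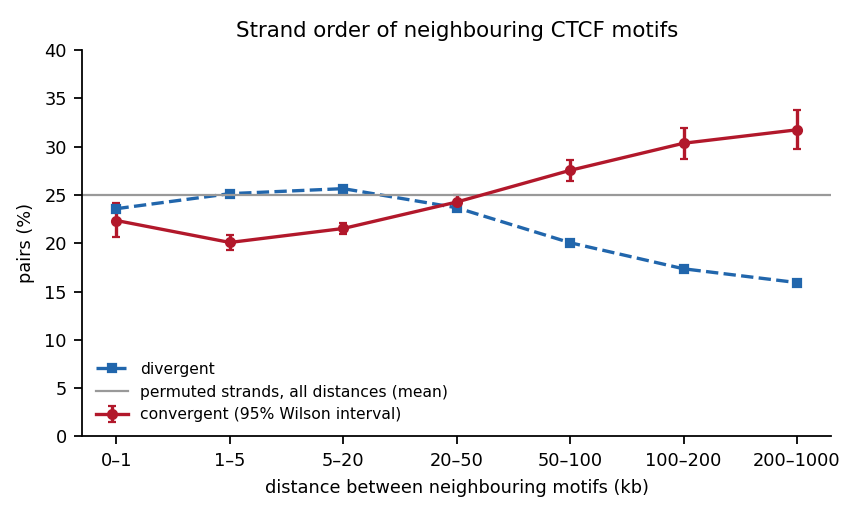
Percent of neighbouring motif pairs (y axis) that were convergent (red, 95% Wilson intervals) or divergent (blue) by the distance between the motifs (x axis, kb). The grey line is the mean of permuted strands over all distances, 25%; convergent pairs pass it from 50 kb on, at 27.6%.

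Among chromosomes 1 to 19 and X, X had the fewest CTCF peaks for its length; Y, with 1 optimal peak, was left out. X held 1695 optimal peaks, or 10.4 per Mb of sequenced bases, against a median of 30.3 over the 19 autosomes, which ranged from 22.8 on chromosome 3 to 46.4 on chromosome 11. The ratio of X to the autosomal median was 0.342 (95% interval 0.326 to 0.358, counting error only). The densest window of 1 Mb lay on chromosome 7 from 19000001 to 20000000 and held 138 peaks among 54 protein-coding genes, including Apoe, Apoc1 and Apoc2 of lipoprotein metabolism, Foxa3 and Ercc1. The widest gap between neighbouring summits lay on X from 24170173 to 35813392. It was 11.6 Mb long, of which 1730610 bases were unsequenced in the assembly, and held 47 protein-coding genes, among them Slx and members of the Spin2 and Btbd35f families.

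Across the 19 autosomes, peak density went with the density of protein-coding genes (Pearson r = 0.864, permutation p = 1e-05; Spearman rho = 0.886, permutation p = 1e-05, in each case the smallest p possible). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.900. This relation, the only correlation across chromosomes computed, was not planned before the data were examined.

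**Figure D5:**
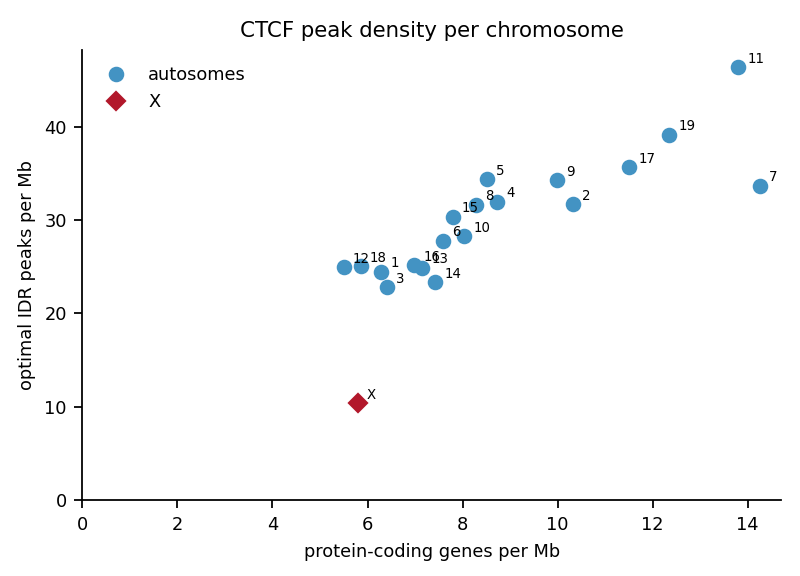
Optimal IDR peaks per Mb (y axis) against protein-coding genes per Mb (x axis) for 19 autosomes (blue) and X (red), each point 1 chromosome. X lies at 10.4 peaks per Mb, below all autosomes, of which chromosome 3 is the lowest at 22.8.

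The replicates placed most optimal peaks alike. Of the 73465 optimal peaks, 89.7% held a summit of the strongest 73465 peaks of replicate 1, 89.8% one of replicate 2, and 84.0% (95% Wilson interval 83.7 to 84.2) held both. Signals of the replicates had a Spearman rho of 0.966 across these peaks, which are not independent replicates, and summits lay a median of 3 bases from the optimal summit. In signal decile 1 the share in both strongest sets was 1.95%, against 100% in decile 10, which follows from the rank limit of 73465, since decile 1 peaks had median ranks of 80865 and 80715 in the replicates. Over whole lists 98.2% of the optimal peaks were in both replicates. The strongest Apob and Cdx2 peaks ranked 1430 and 12216 in replicate 1 and 1211 and 13817 in replicate 2. The optimal list was derived from the lists of these replicates, so these shares are not an independent check of it.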

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

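The pooled list holds many peaks outside the main measurement that still carry a CTCF motif. Among 119114 pooled peaks of the held-out chromosomes that lie outside both IDR lists and overlap no optimal peak, 24.1% (95% Wilson interval 23.9 to 24.3) had a motif. This stands against 5.27% of the windows that flank the optimal peaks. Windows flanking the pooled peaks themselves were not scored. With such peaks of all chromosomes split into 10 signal classes, the share went from 52.0% in the strongest class to 9.79% in the weakest. The share of pooled peaks with a motif was computed after the main results had been seen. No control track was used here, so the windows flanking optimal peaks stand in for a background.

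The optimal list also held 13 peaks on unplaced scaffolds, sequences that no comparison here used. They were not annotated, and no expected number was available to set against them.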

How the results depend on the processing

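The comparison of motif matrices was added after seeing the data; the other alternatives were planned. The promoter share (19.8% to 22.0% over the peak lists), the motif share, the convergent share and the X ratio kept their direction and call in all alternatives run, and the promoter share was 45.7% at 5 kb, 10.4% at 200 bases and 18.2% at TSSs of protein-coding genes. The motif share ranged from 55.3% at the strictest score threshold to 88.6% above the median signal, and was 72.8% with the first matrix, against 76.8% as reported. The convergent share was 23.6% with the first matrix and 23.2% to 24.1% in the others. The X ratio was 0.333 to 0.348.

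Replicate agreement was 84.9% with 1 shared base, 75.2% with reciprocal overlap of 50%, 98.2% over whole lists and 89.3% for the conservative list. Above the median signal the optimal peaks covered 8.86 Mb with a median width of 249 bases, by construction fewer peaks. Of the 18 gene lists 9 were called. The number was 6 in the conservative list, 7 at 2 kb (6 of them also called at 10 kb) and 5 at 50 kb. Above the median signal it was 11, of which 8 were called in the same direction in the optimal list and the protocadherin list in the opposite one. With rotated peaks, which are not matched to genes, it was 18. With rotated peaks the immune list (70.8%) and the list of other organs (66.7%) turned to higher, and above the median signal the protocadherin list (42.9%) turned to lower; the cause was not tested. Calls of 8 and 7 lists were made without replicates 1 and 2. Ribosomal, histone and both receptor lists were called in all of these settings. Of 169 alternatives in all, 134 kept the direction and side of the threshold (for untested values and counts, stayed within the set tolerance), though values moved in many; 13 lost a call, 10 gained one, 9 moved past the tolerance and 3 turned a direction. Unknown read depth limits what can be said of weak peaks.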

Other observations

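The tests of gene density and DNA dose on X and of signal at promoters were chosen after the result was seen. The loci below were also chosen after their values were seen. Among the Hox clusters, whose peak density was not tested, Hoxa held 11 peaks in 125 kb, Hoxb 17 in 194 kb, Hoxd 10 in 117 kb and Hoxc 7 in 136 kb, with median signals of 279, 80.8, 189 and 96.9. In the clustered protocadherin region on chromosome 18, 56 peaks lay in 932 kb with a median signal of 53.3, and of the 33 with a motif 28 pointed along the plus strand and 5 along the minus strand. The apolipoprotein cluster from Apoa1 to Apoa5 on chromosome 9 held 6 peaks, the strongest with a signal of 433 from 46229871 to 46230254.

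Over the genome, 41633 of 128458 strict motif instances (score above the threshold of 1% of flanking windows) lay in an optimal peak (32.4%), 49.1% of those outside repeats masked in the assembly and 19% of those inside. Of motifs in optimal peaks 27.8% lay in masked repeats, 45.2% in signal decile 1 and 5.46% in decile 10.

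X had fewer peaks per Mb than each autosome. Gene density does not account for all of this, since X lay 4.35 residual SDs below the line of the autosomes. Motif supply was lower on X, at 32.4 strict instances per Mb against 37.6 on the lowest autosome. Of the instances on X 20.1% lay in a peak, against 28.6% on the lowest autosome. The number of instances alone is thus argued against as the whole cause. Instances were not matched on score, and the share in a peak was 15.7% in the lowest score decile and 84.8% in the highest. Whether instances on X scored lower was not examined. Masked repeats covered more of X (44.7%, against 35.0% at most on autosomes) and left fewer instances outside them (12.4 per Mb, against at least 17.1). Masked repeats are argued against as the whole cause, since outside them the shares in a peak were 37.7% on X and 41.4% on the lowest autosome. These instances were not matched on score either. The comparison covers only sequence masked in the assembly. Duplicated sequence that is not masked, and whether reads could be placed there uniquely, were not examined. A lower dose of X DNA in male mice of the pools stays open. X peaks with a strict motif had a median signal of 106, below the lowest autosome at 118, which met the prediction written for a lower dose. All X peaks had a median of 80.9, above the autosomal median of 76.4, a measure not in that prediction. Both medians cover only peaks that passed into the optimal list, so they cannot decide the question, and sex was not recorded.

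Promoter peaks lacked a motif more often than other peaks. A strict threshold is argued against as the whole cause. With the loosest threshold run, reached by 10% of flanking windows, the odds ratio of a motif at promoters had an upper bound of 0.354. With the first matrix the odds ratio was 0.301 against 0.311. Both matrices were trained on strong peaks, so sites unlike them can stay uncalled at these thresholds, and this was not tested. Weak signal is argued against as the whole cause, because promoter peaks held a motif less often in 10 of 10 signal deciles. Part of the difference went with CpG content, the odds ratio moving from 0.311 to 0.570 within CpG deciles, with an upper bound of 0.608. Away from promoters, motif-free peaks might mark sites of other intestinal factors, but the HNF4 and GATA words were rare. The HNF4 word lay in 1.39% of 9542 motif-free intronic and intergenic peaks and in 0.615% of those with a motif. For the GATA word these shares were 2.86% and 1.82%. At matched GC the odds ratios were 2.37 (1.92 to 2.93) for HNF4 and 1.66 (1.44 to 1.91) for GATA, against 1.05 and 0.942 for their reversed words. The CDX word had 1.09 (0.994 to 1.2), short of what was set for all 3, and its reversed word 0.884. The AP-1 word, not specific to intestine, had 1.32 (1.19 to 1.46), and its reversed word 1.12. With the CDX word short and peak signal not matched, this stays open.

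From 1 to 5 kb on, the convergent share rose with distance between motifs, while the nearest pairs, under 1 kb, lay above the next class (22.4% against 20.1%). Repeated motif copies in masked sequence do not account for it, since with both motifs outside repeats the share was 18.4% at 1 to 5 kb and 31.6% at 200 to 1000 kb. Weak peaks do not either, as above the median signal the shares were 16.2% and 38.6%. For none of these 3 patterns was a biological explanation tested against a group, since the series has 1 group; loops anchored at convergent motifs may play a part here, but no contact map was used.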
